A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

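RNA abundance was measured in 6 libraries of budding yeast (Saccharomyces cerevisiae, W303 background) in which the RIO1 gene carries an auxin-inducible degron and the plant F-box protein OsTIR1 is expressed from the ADH1 promoter. With this system, auxin directs the tagged Rio1 protein to ubiquitination and proteasomal degradation. Per the labels' protocols, cultures grew exponentially in rich glucose medium (YPD) at 23 °C. The 3 depleted libraries came from cells given 500 µM auxin for 1 h, and the 3 control libraries from the same strain without auxin. The sample titles call the controls wild type and the series description names an isogenic wild-type strain as the comparator, whereas the strain and source fields name the degron strain for both groups. The samples were grouped by the field that states depletion or control. No label names a batch, a pairing or separate cultures, so p-values measure the spread between these libraries, which may be technical in part. No library had auxin with intact Rio1.

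Per the labels' protocols, total RNA was extracted with hot phenol, depleted of rRNA with a yeast Ribo-Zero Gold kit and made into libraries with the ScriptSeq v2 kit. The deposited values are raw counts of reads per gene, 1 column per library, followed by 5 HTSeq summary rows. Per the submitters' processing notes, TopHat2 2.0.8, HTSeq and DESeq were used with the sacCer3 build. The role and settings of each tool, the strand option and the gene annotation are not given in the sources used here. The deposited counts leave out reads with more than 1 alignment, which have their own summary row. This lowers the counts of genes with near-identical copies, which include many ribosomal protein, histone and translation factor genes, so values for such copies are uncertain. Of the 8 genes that lie wholly inside a gene on the opposite strand, 8 had no count in any library, as counting without strand would give. Reads from overlapping or antisense genes therefore cannot be separated.

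Each file held 6692 gene identifiers. The locus tags of 6008 matched the RefSeq table of assembly R64, the assembly known as sacCer3, and the other 684 kept their systematic names. The files carry no coordinates, and those given here come from R64. The summary rows and no other rows were left out of library sizes. No row was named for an rRNA, and 374 genes had no count in any library. Gene counts summed to 683896, 1048376 and 903161 in depleted libraries 1 to 3 and to 788498, 1244756 and 1671136 in control libraries 1 to 3. Before the TMM scaling described below, 1 read is thus worth between 0.60 and 1.46 CPM (counts as a share of the library's gene counts, times 1e6). Reads aligned to more than 1 place made up 45.2% to 65.9% of the entries of a file, reads outside annotated genes 11.0% to 17.9%, and ambiguous reads 0.81% to 1.46%. The 95% Wilson intervals of these shares are at most 0.066 percentage points to either side, and those of the gene shares given in the text at most 0.096. They cover counting error only. Open reading frames annotated inside the rDNA (the YLR154 series) took 4.12% of the gene counts in depleted library 2 and 1.48% in control library 1, against 0.058% to 0.194% in the other 4.

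Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with its minimum count of 10 and minimum total of 15, glmQLFit and glmQLFTest on the 2 groups). All adjusted p-values are Benjamini-Hochberg values from this quasi-likelihood test unless another tool is named, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Log2 fold changes are depleted minus control, and CPM values use the TMM-scaled library sizes. Gene lists were compared with all other tested genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 41 lists with at least 5 tested members, and again with an estimated correlation and with fry. Of the 46 lists written, those of small nucleolar RNAs, tRNAs and Ty genes had no gene in the files. A gene near silent in controls passes the count filter only if it rises, which favours rises in lists of weakly expressed genes. Ribosomal protein genes are the 2 cytosolic lists without RPP1, an RNase P and RNase MRP subunit that the name pattern also took.

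The test, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took RIO1, then the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups, leaving out rRNA, Ty and W303 marker genes. It also took up to 4 members of each list with the largest called change (or the 2 most abundant where none was called) and the gene with the smallest p in each direction. Genes named outside it were chosen after their values were seen, and are said to be. The alternatives were RLE size factors, library totals only, 2 other count filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, ORF names only, libraries thinned to the smallest total, an adjusted p under 0.01, glmTreat against 1.5-fold, and each library left out in turn. Leaving out the YLR154 rows was added after the data were seen. Keeping rRNA rows was planned but had no row to act on.

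The scripts were tested on simulated data with 200 genes changed by known folds, drawn from the means and sizes of these libraries. Over the 5140 genes run, edgeR recovered 55.7% of 1.5-fold, 87.5% of 2-fold and 98.4% of 3-fold changes, with 11 false calls (6.71% of calls). The 200 genes changed in random directions, so this does not check the scaling when many abundant genes fall together. The list test called the raised list and 0 of 40 unchanged lists, in data whose genes vary independently, so it does not check the effect of correlated genes on the list calls. Shares of gene counts were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Other permutation tests and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.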

Results

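The 6 libraries were compared to ask which genes change in abundance when yeast lose Rio1, an essential protein kinase that acts in the maturation of the small ribosomal subunit and at the rDNA. The 3 depleted libraries came from cells given 500 µM auxin for 1 h and the 3 control libraries from cells without auxin. Gene counts per library ran from 683896 to 1671136. On the first principal component of the log CPM values, which held 61.2% of the variance, the depleted libraries lay between -23.3 and -19.6 and the control libraries between 20.3 and 23.6. No pair of libraries held identical values, and libraries of one group differed by more than sampling noise, with chi-square values of 2.59 to 11.2 per degree of freedom. The highest values, 8.83 and 11.2, were those of depleted library 2 with the other depleted libraries. The YLR154 rows, which took 4.12% of the gene counts of depleted library 2, were kept in this calculation. Those values are therefore not a spread shared by all genes.

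The mRNA of the targeted gene rose. RIO1 (YOR119C, chromosome XV, 548792 to 550246, R64) stood at 66.0, 66.6 and 63.1 CPM in control libraries 1 to 3 and at 130.2, 112.7 and 94.0 CPM in depleted libraries 1 to 3. Its log2 fold change was 0.78 ± 0.17 (SE, n = 3 per group), or 1.71-fold, with an edgeR adjusted p of 0.00159. The degron acts on the protein, so this mRNA level does not check the depletion. The titles call the controls wild type, so the labels leave open whether the groups also differ in strain. The call was lost when the fold was tested against 1.5-fold (glmTreat, adjusted p = 0.355).

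Across the genome, most ribosomal protein genes and many amino acid biosynthesis genes fell, while most genes of the proteasome and Hsf1 chaperone lists rose. Of 5195 genes tested, 734 were higher and 735 lower in depleted cells, together 28.3% of the genes, and 248 of the higher and 197 of the lower changed at least 2-fold. The 2 groups did not overlap for 2110 tested genes (40.6%), against 10% by chance. These counts are relative to TMM scaling. With library totals only, the median of all genes moved up by 0.315 on the log2 scale and the split became 1761 higher and 306 lower (85.2% of calls higher, against 50.0%), so a change close to 0 has a direction only relative to that choice. Of 41 gene lists, camera called 9 higher and 12 lower. Of these 21 calls, 6 held with an estimated inter-gene correlation (both ribosomal protein lists, proteasome, Hsf1 chaperones, sulfur assimilation and respiration), and all 21 were among the 29 called by fry, which asks whether the members changed at all and not whether they changed more than other genes. With the preset correlation, camera also called 7 to 18 lists in splits of the libraries that mix the 2 groups, where no gene was called. A camera call in that setting is therefore weak support by itself.

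**Figure D1:**
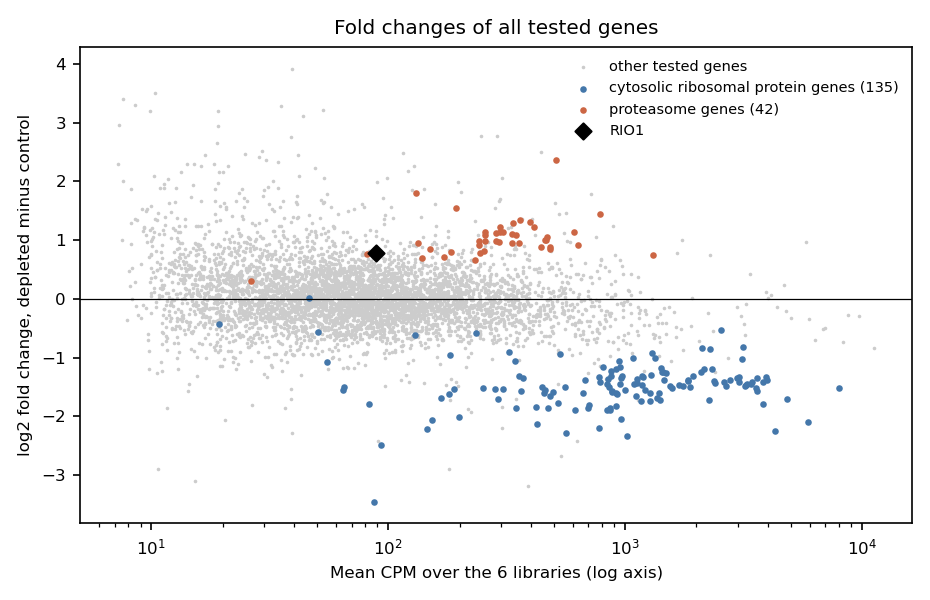
Log2 fold change (depleted minus control) against mean CPM over the 6 libraries (log axis), 1 point per tested gene; blue points are the 135 cytosolic ribosomal protein genes, orange points the 42 proteasome list genes and the diamond is RIO1. Of the ribosomal protein genes 132 were called lower, and of the proteasome genes 41 were called higher; under library totals only, 129 and 41 were.

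Transcripts for the proteins of the cytosolic ribosome fell as a block. Ribosomal protein genes took 24.9% ± 0.23 of the gene counts in control libraries and 11.4% ± 0.15 in depleted libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). All 56 small-subunit genes were lower, with a median log2 fold change of -1.45. Of 80 tested genes on the large-subunit list, 76 were lower, with a median of -1.48, and the counts adjusted over the list alone were the same for both lists. RPP1, the only one higher (log2 fold change 0.61), encodes a subunit of RNase P and RNase MRP and not of the ribosome. RPL33A, RPL41B and RPL15B did not pass the test, with log2 fold changes of -0.56, -0.42 and 0.01 (these 4 genes were named after their values were seen). The ribosomal protein genes made up 18.0% of all genes called lower.

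Among small-subunit genes the largest falls were in RPS3 (-2.26 ± 0.13, SE), RPS7B (-2.20 ± 0.16), RPS9A (-2.14 ± 0.14) and RPS31 (-2.09 ± 0.11), the last of which encodes a ubiquitin fused to a ribosomal protein. On the large-subunit side RPL7B (YPL198W, chromosome XVI, 173152 to 174702) fell from 160 ± 19.7 to 14.4 ± 2.91 CPM (SD, n = 3 each), 11.0-fold, with an edgeR adjusted p of 5.595e-10. Its span holds a noncoding RNA gene, whose reads are not separable from its own. RPL22B fell 5.59-fold, RPL31B 5.03-fold and RPL42A 4.85-fold. Most of these genes have a paralog, and reads that align equally well to both copies are not in the counts. Both lists were lower by camera (adjusted p = 3.314e-55 for the small and 4.781e-67 for the large subunit) and also with an estimated correlation (adjusted p = 0.00257 and 0.00083).

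**Figure D2:**
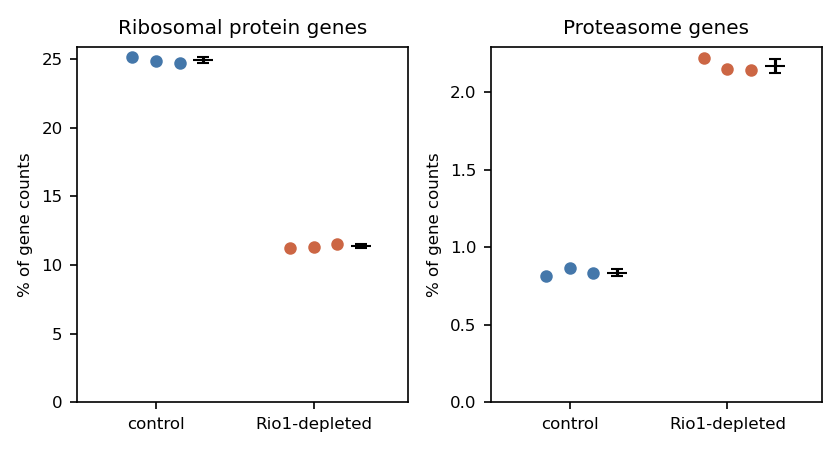
Percent of gene counts taken by cytosolic ribosomal protein genes (left) and by the proteasome list (right) in each library; points are libraries, and black marks are the mean and SD of 3. Ribosomal protein genes went from 24.9% to 11.4% and proteasome genes from 0.837% to 2.17%, with no overlap between the groups.

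Genes of the proteasome rose together. Of 42 genes on the list, which holds core and regulatory particle subunits and associated factors, 41 were higher and none lower, also when adjusted over the list alone, with a median log2 fold change of 0.98. The exception was the assembly chaperone RPN14 (0.30), named after its value was seen. The list's share of gene counts went from 0.837% ± 0.025 to 2.17% ± 0.044 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). ECM29 (YHL030W, chromosome VIII, 40084 to 45690), a proteasome-associated scaffold and the higher gene with the smallest p, rose from 165 ± 1.76 to 853 ± 45.8 CPM (5.15-fold, edgeR adjusted p = 7.57e-11). The shuttle factor DDI1 rose 3.48-fold, UFD1, a Cdc48 cofactor, 2.90-fold and BLM10, a proteasome activator, 2.72-fold. UBI4 (YLL039C, chromosome XII, 64062 to 65207), the polyubiquitin gene, rose from 75.1 ± 17.2 to 499.5 ± 55.1 CPM (6.85-fold, edgeR adjusted p = 7.57e-11). Reads that align equally well to other ubiquitin genes are not in its counts. The proteasome list was higher by camera (adjusted p = 2.547e-40) and with an estimated correlation (adjusted p = 0.00484).

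Chaperone genes controlled by the heat shock factor Hsf1 also rose. Of 29 genes, 23 were higher and 1 lower (24 and 1 adjusted over the list alone), with a median of 0.60. The small heat shock protein gene HSP42 rose 4.78-fold, the Hsp70 gene SSA1 4.16-fold, the Hsp90 gene HSP82 3.43-fold and BTN2, whose product sorts misfolded proteins, 2.63-fold. The gene that fell was the Hsp40 gene APJ1, with a log2 fold change of -0.53. Its fall was not called with library totals only, where 27 genes of the list were higher and none lower. HSC82 and SSA2, the constitutive partners of HSP82 and SSA1, did not pass the test (0.11 and 0.23). These last 3 genes were named after their values were seen. Reads that align equally well to a gene and its partner are not in the counts, so the contrast within each pair is uncertain. The list was higher by camera (adjusted p = 3.817e-11) and with an estimated correlation (adjusted p = 0.0287).

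Many genes of amino acid biosynthesis that the activator Gcn4 controls fell. Of 57 tested, 35 were lower and 3 higher (37 and 3 adjusted over the list alone), with a median of -0.64; with library totals only 25 were lower and 3 higher, with a median of -0.32. The largest fall was in ARG1 (YOL058W, chromosome XV, 219211 to 220473), argininosuccinate synthase, which fell from 701 ± 97.7 to 77.3 ± 7.96 CPM (SD, n = 3 each), 9.10-fold with an edgeR adjusted p of 1.865e-11, the smallest p of all genes that fell. ARG3 fell 7.42-fold and ARG56, which encodes 2 arginine enzymes in 1 precursor, 5.35-fold. GLN1, glutamine synthetase, fell 6.41-fold. The 3 genes higher were GCV1, GCV2 and GCV3, subunits of the glycine cleavage complex, with log2 fold changes of 0.71, 0.83 and 0.53 (GCV3 was named after its value was seen). The list was lower by camera (adjusted p = 2.489e-21), a call not kept with an estimated correlation (adjusted p = 0.0764).

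Of 29 tested genes of sulfur assimilation, 14 were lower and 3 higher, also when adjusted over the list alone, with a median of -0.60 (camera adjusted p = 4.589e-06; adjusted p = 0.0411 with an estimated correlation). Scaled by library totals only, 10 were lower and 3 higher. STR3, a cystathionine beta-lyase gene, fell from 27.5 ± 2.65 to 2.95 ± 2.15 CPM (8.56-fold, edgeR adjusted p = 2.501e-05). MET17, which makes homocysteine from sulfide, fell 5.38-fold and the methionine synthase gene MET6 3.29-fold, and MET17 overlaps another annotated gene (YLR302C). JLP1, a sulfonate dioxygenase gene, rose 2.78-fold. Of 25 targets of nitrogen catabolite repression, 5 were lower and 3 higher, also when adjusted over the list alone. The general amino acid permease gene GAP1 fell 3.66-fold, the ammonium permease gene MEP2 2.25-fold and GLN1 is on this list too, whereas the urea permease gene DUR3 rose 2.24-fold. That list was lower by camera (adjusted p = 0.028), not with an estimated correlation (adjusted p = 0.178) without depleted library 2 (adjusted p = 0.119) or in limma-voom (adjusted p = 0.126). Its median, -0.15, turned to 0.16 with library totals only, where 3 genes were lower and 4 higher.

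Of 19 glycolysis and fermentation genes, 13 were lower and none higher, also when adjusted over the list alone, with a median of -0.47. The largest fall was in ADH5, a minor alcohol dehydrogenase gene, at 4.85-fold, followed by the enolase gene ENO1 (1.82-fold), the pyruvate decarboxylase gene PDC1 (1.78-fold) and the phosphofructokinase gene PFK1 (1.53-fold). With library totals only, 3 of the 19 were lower and the median was -0.15. Of 20 tested genes repressed by glucose, 11 were higher and none lower (14 and 0 adjusted over the list alone; 18 and 0 with library totals only), with a median of 0.85. Genes near silent in controls pass the count filter only if they rise, so the tested set favours rises. With no count filter, 14 of 34 were higher and none lower. ADR1 (YDR216W, chromosome IV, 895035 to 899006), an activator of ethanol and fatty acid use, rose from 64.8 ± 16.0 to 427 ± 41.1 CPM (6.82-fold, edgeR adjusted p = 1.083e-10). IDP2, cytosolic isocitrate dehydrogenase, rose 5.49-fold, the acetyl-CoA synthetase gene ACS1 4.00-fold and GAL1, which overlaps another annotated gene (YNCB0008W), 3.01-fold. By camera glycolysis was lower (adjusted p = 0.00324) and the glucose-repressed list higher (adjusted p = 1.447e-06). Neither call was kept with an estimated correlation (adjusted p = 0.472 and 0.0938).

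Of 51 genes of the TCA cycle and the respiratory chain, 20 were lower and 1 higher (23 and 1 adjusted over the list alone). The cytochrome oxidase genes COX6 and COX4 fell 2.13-fold and 1.89-fold, the cytochrome c gene CYC1 1.73-fold and NDE1, an NADH dehydrogenase gene, 1.70-fold. IDH1, the gene that rose (log2 fold change 0.52), was named after its value was seen. The list was lower by camera (adjusted p = 0.000118) and with an estimated correlation (adjusted p = 0.0477). Its median of -0.34 came to -0.02 with library totals only, where 6 genes were lower and 4 higher. Of 10 tested genes on the hexose transporter list, which also holds the sensors RGT2 and SNF3 and the regulators MTH1 and STD1 (named after their values were seen), 1 was higher and 2 lower, also when adjusted over the list alone. HXT3 and HXT1 fell by 0.95 and 0.68 on the log2 scale while HXT11, a member of a near-identical family, rose 4.92-fold. That list was not called (camera adjusted p = 0.644).

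Of 46 cell cycle genes expressed at G1/S, 20 were lower and 1 higher (22 and 1 adjusted over the list alone), with a median of -0.50. Scaled by library totals only, 7 were lower and 2 higher, with a median of -0.18. The G1 cyclin genes CLN2 and CLN1 fell 2.47-fold and 2.14-fold, the bud site gene AXL2 1.93-fold and the repressor gene YOX1 1.84-fold. RFA1, a subunit of the single-strand DNA binding complex, rose (log2 fold change 0.45; named after its value was seen). Of 9 histone genes, 7 were lower and none higher, also when adjusted over the list alone, led by HHF2, HHT2, HHF1 and HHT1 with log2 fold changes of -0.72, -0.71, -0.63 and -0.58, whose copies are near-identical. Only 2 histone genes were lower under library totals only, and the median went from -0.57 to -0.25. Camera called both lists lower (adjusted p = 4.262e-05 for G1/S and 0.00396 for histones), and neither call was kept with an estimated correlation (adjusted p = 0.0764 and 0.217).

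Of 28 genes of the G2/M cluster, 9 were lower and 1 higher, also when adjusted over the list alone. The mitotic cyclin genes CLB4 and CLB2 fell 1.76-fold and 1.57-fold. Other called members included the plasma membrane proton pump genes, PMA1 (1.64-fold lower) and PMA2 (2.38-fold higher). Also lower were TEM1 (-0.63), PMP1 (-0.62), BUD3 (-0.55), BUD4 (-0.42), CHS2 (-0.40) and CDC5 (-0.33), named after their values were seen. The list was lower by camera (adjusted p = 0.0241), not with an estimated correlation (adjusted p = 0.206) without depleted library 3 (adjusted p = 0.0563) or with a mean of at least 50 counts (adjusted p = 0.0569). With library totals only the call was also lost (adjusted p = 0.0605) and the median of -0.29 turned to 0.02, with 1 gene lower and 3 higher. Of 31 M/G1 genes, 7 were lower (4 adjusted over the list alone), including SUN4, SWI4, CLN3 and DSE2 with log2 fold changes of -0.75, -0.55, -0.54 and -0.40, and the list was not called (camera adjusted p = 0.112). When 1 library was left out, 2 to 7 M/G1 and 5 to 9 G2/M genes were lower, and DESeq2 called 4 G2/M genes lower. In the kinetochore list, 2 of 49 genes were higher (1 adjusted over the list alone), SPC105 (0.87) and IML3 (0.86), and the list was not called (camera adjusted p = 0.875).

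Most ribosome assembly genes did not pass the test. Of 18 small-subunit processome genes, 5 were higher and 1 lower, with UTP25 at 0.75, UTP21 at 0.58, UTP11 at 0.57 and UTP22 at -0.70. Of 20 late 40S maturation factors, the step at which Rio1 acts, 3 were higher and none lower, namely the rRNA methylase gene DIM1 (0.63), the export adaptor gene LTV1 (0.41) and the kinase gene CKA2 (0.34). In the 60S list 8 of 61 were higher, among them NOP8 (0.67), DBP2 (0.56), BRX1 (0.46) and DBP7 (0.41). In the nucleolar and early processing list 12 were higher and 2 lower of 43, with DHR2 at 0.79, DIP2 at 0.78, DBP8 at 0.59 and CBF5, the pseudouridine synthase gene, at -0.58. Adjusted over the list alone, 5 processome, 1 late 40S, 6 60S and 12 nucleolar genes were higher. When 1 library was left out, 3 to 6 processome, 1 to 5 late 40S, 2 to 9 60S and 6 to 10 nucleolar genes were higher, and DESeq2 called 4, 1, 5 and 7. None of these lists was called by camera (adjusted p = 0.177, 0.248, 0.199 and 0.0935). With library totals only the processome, 60S and nucleolar lists were called higher (adjusted p = 0.0387, 0.0217 and 0.0112), with 14, 41 and 28 genes higher and 12 of the late 40S list, and the 60S list was called without depleted library 3 (adjusted p = 0.0499). The nucleolar list was also called higher with a mean of at least 50 counts (adjusted p = 0.0492) and in limma-voom (adjusted p = 0.0486).

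RNA polymerase I genes gave 4 higher of 18 (3 adjusted over the list alone), RRN3 (0.76), RRN6 (0.67), RPC19 (0.56) and RPA49 (0.30), with a camera adjusted p of 0.111, or 0.0499 without depleted library 3. None of 20 RNA polymerase III genes was called, and the most abundant, RPO31 and RET1, had log2 fold changes of -0.29 and 0.05 (camera adjusted p = 0.799). Of 17 rDNA silencing genes 1 was higher and 2 lower, HDA1 (0.62), SIR4 (-0.55) and TOP1 (-0.48), with a camera adjusted p of 0.644. Of 74 mitochondrial ribosomal protein genes only MRPL32 was called (0.45), and none was when adjusted over the list alone (camera adjusted p = 0.347). With library totals only, 29 mitochondrial ribosomal protein, 13 RNA polymerase I, 9 RNA polymerase III and 17 exosome and TRAMP genes were higher and none lower, and 5 rDNA silencing genes were higher and none lower. Of 21 nuclear exosome and TRAMP genes 5 were higher, also when adjusted over the list alone, including the poly(A) polymerase gene TRF5 (0.63) and the exosome genes RRP46 (0.57), RRP40 (0.53) and RRP6 (0.41). Leaving out 1 library gave 2 to 4 RNA polymerase I and 2 to 5 exosome and TRAMP genes higher. The exosome list was higher by camera (adjusted p = 0.0464). That call ended with an estimated correlation (adjusted p = 0.206), without depleted library 2 (0.0898), control library 1 (0.0628) or control library 3 (0.09), without the YLR154 rows (0.0502) and with no count filter (0.0508).

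Of 36 translation factor genes 16 were lower and 1 higher (17 and 2 adjusted over the list alone), led by the elongation factor gene EFT2 (2.07-fold), the eIF4A genes TIF2 (1.76-fold) and TIF1 (1.69-fold), which are near-identical, and YEF3 (1.66-fold). Of 22 aminoacyl-tRNA synthetase genes 13 were lower and none higher (15 and 0 adjusted over the list alone), with CDC60, the leucine enzyme, at 1.96-fold, YHR020W at 1.63-fold, DED81 at 1.57-fold and KRS1 at 1.46-fold. Camera called both lists lower (adjusted p = 0.0155 and 0.00352), not with an estimated correlation (adjusted p = 0.278 and 0.189). The median of the translation factors, -0.26, turned to 0.06 with library totals only, which also ended that list's call (adjusted p = 0.0872), as did a mean of at least 50 counts (adjusted p = 0.0801), while that of the synthetases went from -0.36 to -0.04. In that setting 4 translation factor genes were lower and 6 higher, and 3 synthetase genes were lower and 2 higher.

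**Figure D3:**
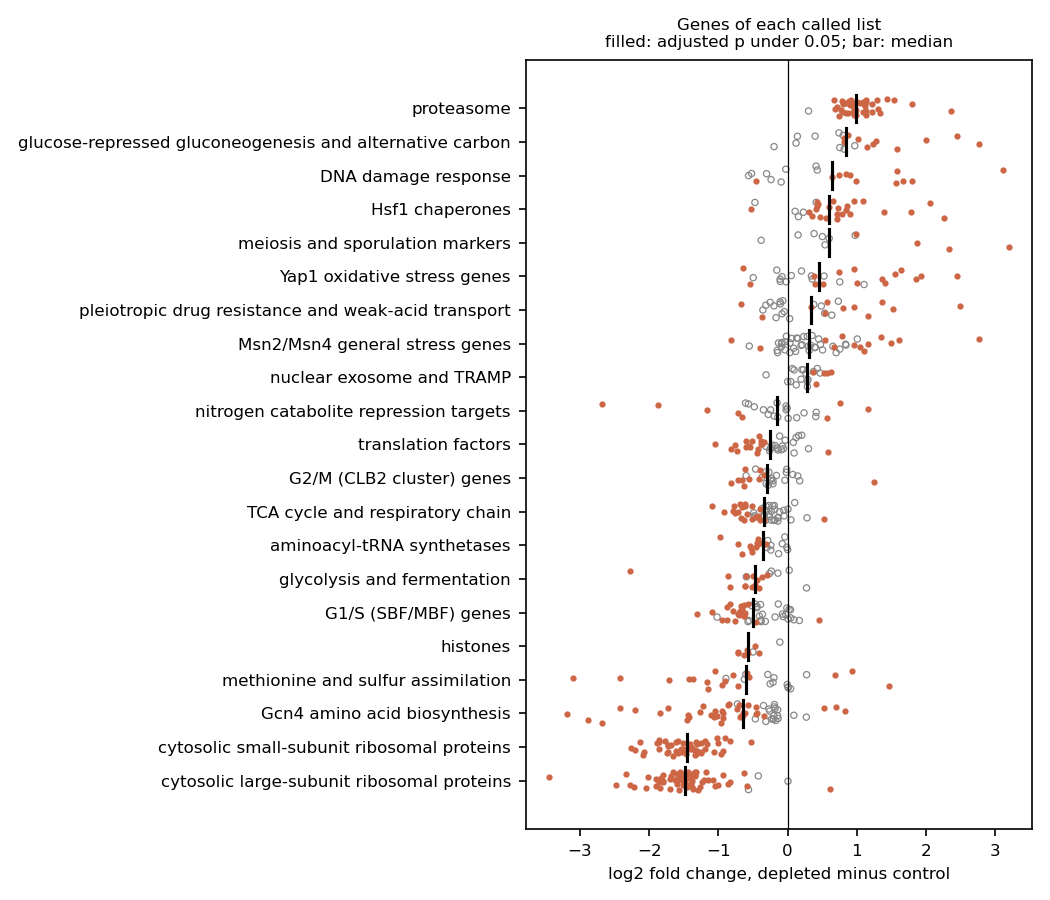
Log2 fold change (depleted minus control) of each tested gene in the 21 lists called by camera, 1 point per gene; filled points passed an adjusted p under 0.05, open points did not, and the black bar is the list median. Medians run from -1.48 for the large ribosomal subunit to 0.98 for the proteasome; with library totals only, those of translation factors, G2/M genes and nitrogen catabolite repression targets turn positive.

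Some genes of several stress-related lists rose. Of 28 genes controlled by the oxidative stress regulator Yap1, 13 were higher and 2 lower (14 and 2 adjusted over the list alone). AAD6 rose 5.47-fold, AAD4 3.81-fold, the methylglyoxal reductase gene GRE2 3.64-fold and YDL218W 3.11-fold, and the AAD genes belong to a family of near-identical copies. Of 49 general stress genes controlled by Msn2 and Msn4, 11 were higher and 2 lower (11 and 1 adjusted over the list alone), led by UBI4, the peroxiredoxin gene PRX1 (3.07-fold), the glycogen debranching gene GDB1 (2.81-fold) and SDP1 (2.56-fold), while CTT1 and HSP12, widely used markers of this response, did not pass the test (-0.01 and 0.48; named after their values were seen). Of 27 drug resistance and weak-acid transport genes, 9 were higher and 2 lower (10 and 2 adjusted over the list alone). PDR12 (YPL058C, chromosome XVI, 445842 to 450377), the exporter of weak organic acids, rose from 132 ± 6.26 to 749 ± 115.9 CPM (5.65-fold, edgeR adjusted p = 1.105e-10), QDR1 rose 2.88-fold, ATR1 2.59-fold and SPI1 2.25-fold. Camera called these lists higher (adjusted p = 0.00107 for Yap1, 0.00569 for Msn2/Msn4 and 0.028 for drug resistance), and none of the calls was kept with an estimated correlation (adjusted p = 0.0764, 0.206 and 0.278). Scaled by library totals only, 18 Yap1, 25 Msn2/Msn4 and 14 drug resistance genes were higher and 0, 1 and 0 lower. Leaving out 1 library gave 7 to 10 Msn2/Msn4 and 5 to 8 drug resistance genes higher. The drug resistance call also ended without depleted library 3 (adjusted p = 0.0554) or control library 3 (adjusted p = 0.0524), in limma-voom (adjusted p = 0.0515) and in thinned libraries (adjusted p = 0.0525). With a mean of at least 50 counts it ended too (adjusted p = 0.061), and the median turned from 0.34 to -0.01.

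Of 19 DNA damage response genes 10 were higher and 1 lower (11 and 1 adjusted over the list alone). MAG1 (YER142C, chromosome V, 455146 to 456036), a DNA glycosylase gene that lies head to head with DDI1, rose from 8.64 ± 1.87 to 78.7 ± 17.4 CPM (8.69-fold, edgeR adjusted p = 7.709e-08). DIN7 rose 3.17-fold and RNR3 3.01-fold, whereas RNR2, another ribonucleotide reductase gene, was the 1 that fell (-0.46; named after its value was seen). The fall of RNR2 was not called with library totals only, where 11 genes of the list were higher and none lower. DDI1 is also on the proteasome list. Of 11 tested markers of meiosis and sporulation, 4 were higher and none lower, also when adjusted over the list alone: the recombination gene REC104 (9.21-fold), GAS2 (5.04-fold), SPS100 (3.65-fold) and NDT80 (1.98-fold). REC104 and SPS100 rose from control means of only 3.74 and 3.88 CPM, and SPS100 overlaps another annotated gene (YNCH0011W). Genes this weak in controls pass the count filter only if they rise, so the tested set favours rises. With no count filter, 7 of 35 meiosis and sporulation markers were higher and none lower. Camera called both lists higher (adjusted p = 0.000341 and 0.0084), not with an estimated correlation (adjusted p = 0.0754 and 0.126). The meiosis call also ended with library totals only (adjusted p = 0.052) and without depleted library 3 (adjusted p = 0.0612), and with a mean of at least 50 counts no member was left to test.

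None of the remaining lists was called. Of 22 genes of the unfolded protein response 4 were higher and 5 lower (6 and 5 adjusted over the list alone), among them ERO1 (0.75), PDI1 (0.67), SCJ1 (0.54) and HAC1 (-0.62), with a camera adjusted p of 0.875. Adenine and one-carbon genes gave 4 higher and 6 lower of 15 (5 and 6 adjusted over the list alone), including ADE17 (-0.86), ADE3 (-0.69) with GCV2 (0.83) and GCV1 (0.71) higher (camera adjusted p = 0.743). Iron regulon genes gave 4 higher and 7 lower of 28, also when adjusted over the list alone, with FRE5 (1.30) and FRE2 (1.09) higher and FIT2 (-1.29) and FIT3 (-0.95) lower (camera adjusted p = 0.248). In the phosphate regulon 6 of 16 were lower, including the phosphate transporter gene PHO84 (from 130.1 to 64.2 CPM), VTC3 (-0.88), KCS1 (-0.68) and VTC2 (-0.48), with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0935). PHO84 overlaps another annotated gene (YNCM0001W). Of 24 ergosterol genes 6 were lower, also when adjusted over the list alone, led by ERG1 (-0.81), ERG11 (-0.74), ERG4 (-0.64) and ERG26 (-0.50), with a camera adjusted p of 0.199. Cell wall integrity targets gave 8 lower and 2 higher of 26, also when adjusted over the list alone, including SVS1 (-0.97), GAS1 (-0.63), SED1 (-0.61) and GSC2 (0.57), with a camera adjusted p of 0.248. The medians of the phosphate, iron, ergosterol, cell wall, adenine, M/G1, kinetochore, rDNA silencing, hexose transporter, W303 marker and unfolded protein response lists, all below 0, lay above 0 with library totals only. There the unfolded protein response list had 9 genes higher and 1 lower, ergosterol 9 and 2, cell wall integrity 8 and 1, kinetochore 9 and 0 and M/G1 4 and 1. In that setting adenine and one-carbon genes gave 6 higher and 2 lower, the iron regulon 6 and 5 and the phosphate regulon 3 and 3. Leaving out 1 library gave 3 to 8 ergosterol and 4 to 9 cell wall integrity genes lower, 1 to 5 iron regulon genes higher, and 2 to 4 unfolded protein response genes in each direction.

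Mating pheromone genes gave 2 higher and 3 lower of 24 (1 and 2 adjusted over the list alone; 9 and 0 with library totals only). PRM1, a membrane fusion gene, rose 6.75-fold and SST2 1.42-fold, while GIC2 and SCW10 fell 1.70-fold and 1.54-fold (camera adjusted p = 0.663). SAG1, the 1 tested marker of the other mating type, rose 1.78-fold (edgeR adjusted p = 0.0394). The call was lost in DESeq2 (adjusted p = 0.083), in libraries thinned to the smallest total (0.249), against 1.5-fold in glmTreat (0.521), and when any single library other than control library 2 was left out. Of 10 stationary-phase genes 2 were higher, also when adjusted over the list alone, SPS100 (3.65-fold) and SSA3 (1.82-fold), with a camera adjusted p of 0.746. None of 3 tested anaerobic genes was called, HEM13 (-0.12) and COX5B (-0.48) being the most abundant. Of 6 W303 auxotrophic marker genes only LEU2 was called, with a fall of 2.46-fold, also when adjusted over the list alone (camera adjusted p = 0.248), a change to be read with the doubt about the control strain. ADE2, TRP1, CAN1, HIS3 and URA3 had log2 fold changes of -0.72, 0.53, -0.35, -0.003 and -0.19 (named after their values were seen).

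Among the largest single rises, YDR215C, an open reading frame of unknown function, rose 15.1-fold from 3.94 ± 3.72 to 74.4 ± 15.7 CPM (SD, n = 3 each; edgeR adjusted p = 1.77e-07). It lies on chromosome IV at 894089 to 894502, head to head with ADR1. YMR194C-A rose 11.4-fold, IZH4, which is linked to zinc and membrane homeostasis, 9.73-fold, YDR042C 9.33-fold and YBR284W 7.69-fold, all from means under 10 CPM. YMR194C-A has no match in the R64 table. The largest fall outside these groups was in YLR264C-A (7.48-fold, edgeR adjusted p = 0.000141), a short open reading frame on chromosome XII at 673828 to 673944. It lies near the ribosomal protein gene RPS28B on the opposite strand, so its counts are uncertain.

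**Figure D4:**
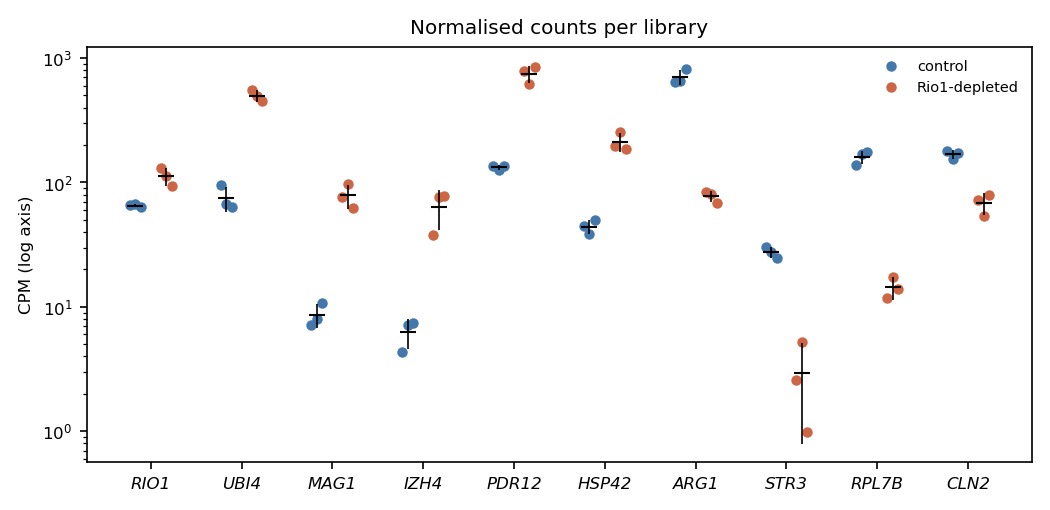
CPM (log axis) of 10 genes in each library; points are libraries, and black marks are the mean and SD of 3. In depleted cells RIO1, UBI4, MAG1, IZH4, PDR12 and HSP42 lie above the controls, and ARG1, STR3, RPL7B and CLN2 below, with no overlap between the groups.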

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

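Leaving out the YLR154 rDNA open reading frames was chosen after the data were seen; the other alternatives were planned. No called gene named by the fixed rule changed direction in a setting that tested it. Of 155 such genes besides RIO1, called or not, 114 were tested with a mean of at least 50 counts, 149 in thinned libraries and all in the others. The call was lost for 23 with library totals only, 16 in DESeq2, 10 in thinned libraries, 22 at an adjusted p under 0.01, 86 in glmTreat and 10 to 22 with a library left out, and for 0 to 4 in the rest. The medians of several lists did with library totals only, among them 3 called lists (translation factors, G2/M genes and nitrogen catabolite repression targets), and that of the drug resistance list did with a mean of at least 50 counts. Medians of uncalled lists turned in other settings too, among them hexose transporters to 0.55 with no count filter and stationary phase to -0.25 in thinned libraries. With a mean of at least 50 counts, mating pheromone turned to -0.07, unfolded protein response to 0.03 and kinetochore to 0.01. The counts of 734 genes higher and 735 lower moved by over 1.5 times under 3 settings. Library totals only gave 1761 and 306, because 1 factor per library moves every gene alike. A stricter threshold (adjusted p under 0.01) gave 457 and 477 with 16 lists, and glmTreat against 1.5-fold gave 204 and 190, both by construction. Under glmTreat the RIO1 log2 fold change of 0.777 no longer passed (adjusted p = 0.355). Of the 21 gene lists called, 6 were called by camera with an estimated correlation, where the spread of each list's own residuals sets the error. With each library left out in turn, 529 to 669 genes were higher, 591 to 699 lower, 19 to 21 lists were called and RIO1 had log2 fold changes of 0.665 to 0.887. The other settings gave 550 to 744 higher, 598 to 793 lower and 17 to 21 lists. With a mean of at least 50 counts, the glucose-repressed list had too few members for camera and the meiosis list none. Where single list calls changed between them, the cause was not tested. DESeq2 and glmTreat give no camera value, and keeping rRNA rows was not run because the files hold none. Depth limits small changes: in libraries thinned to the smallest total, 584 genes were higher and 660 lower.

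With the replicate number as a block, 741 genes were higher and 756 lower, 21 lists were called and RIO1 had a log2 fold change of 0.756. The numbers gave no strong sign of pairing: deviations from the group means had correlations of -0.057, -0.001 and 0.077 for numbers 1, 2 and 3, and not every library correlated best with its own number. With 3 libraries per group, a weak shared effect would not show.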

Other observations

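The tests of library scaling, paralogous copies, repeated gene families, auxin, other splits, paralog abundance and introns were chosen after the results were seen, as were the idea of looking near chromosome ends, its 25 kb window and all genes named in this part.

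Of single genes of the ubiquitin system outside the proteasome list, 10 were chosen after their values were seen and all were higher, a count that says nothing about the group. The largest rises were in UBI4 (polyubiquitin), TMC1 (4.51-fold), CUZ1 (3.53-fold), UBR2 (3.07-fold), UBX4 (2.88-fold) and the shuttle factor gene DSK2 (2.29-fold). Among regulator genes, RPN4, the activator of proteasome genes, and YAP1 each rose 1.80-fold, while GCN4 fell by 0.93, MSN2 by 0.57 and RAP1 by 0.42 on the log2 scale. In all, 4 of 12 regulator genes were higher and 3 lower. Of 12 amino acid permease genes 6 were lower, led by AGP1 (3.79-fold), GAP1 (3.66-fold) and MUP1 (2.57-fold), and 2 were higher, AGP3 (5.15-fold) and HIP1 (1.92-fold). Of 5 genes of aromatic amino acid catabolism, ARO9 (4.69-fold), ARO10 (2.94-fold) and ARO80 (1.54-fold) rose and ARO8 fell (1.27-fold). Among 4 genes of biotin synthesis and uptake, BIO2 rose 3.96-fold and VHT1 fell 1.89-fold.

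The fall of ribosomal protein genes was weighed against 3 technical explanations. Their median log2 fold change lay at -1.502 relative to that of all other genes (75th percentile -1.348). A change of the library scaling cannot make such a gap, since 1 factor per library moves every gene alike. The gap restates the fall that was already seen and is no separate test. Set against the trend of all other genes on GC content and gene length, their median was -1.526 (75th percentile -1.362), which argues against that bias. The 19 ribosomal protein genes with no second copy, all called lower, had a median of -1.436 (75th percentile -1.304), which argues against reads shared between paralogous copies. The fall may be a change in the cells, a hypothesis found and tested on the same data. A difference in preparation between the groups was not tested, and whether auxin, Rio1 loss or a difference in strain brings the fall is open.

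Genes within 25 kb of a chromosome end, ribosomal protein genes aside, were called higher more often than others: 38 of 130 (29.2%, 95% Wilson interval 22.1 to 37.6) against 691 of 4841 (14.3%, 13.3 to 15.3). They include AGP3, YCR102C, FLO1, MAL11, ZRT1 and PHR1; the share was 33.3% within 15 kb, 22.7% within 50 kb and 16.4% within 100 kb, and 29.6% against 13.5% for genes on no fixed list. Of 10000 random sets of tested genes matched on mean CPM over both groups, whose average was 13.4% and highest 24.6%, none reached the end genes' share (permutation p = 0.0001, the smallest possible, or 0.01% with the real set counted). These sets cannot decide on low expression, since a gene near silent in controls passes the count filter only if it rises. AGP3, YCR102C, FLO1, MAL11 and PHR1 had control means of 4.78 to 9.90 CPM, and ZRT1 281 CPM. Neighbouring genes were also taken as independent. Outside the repeated families COS, PAU, FLO, MAL, IMA, HXT, AAD, YRF and SEO, 27.679% were higher (31 of 112, 20.2 to 36.6). This argues against reads shared within those families as the whole source, although the family pattern was narrowed after a first run. It cannot decide on other repeated genes, which were kept in this set. No biological explanation of this pattern was tested.

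Auxin itself rather than loss of Rio1 could account for any of these changes, since the number of libraries with auxin and intact Rio1 was 0. Auxin and loss of Rio1 cannot be told apart in this design. If the controls were a wild type without the degron, as their titles say and their strain fields do not, strain would differ as well, which bears on RIO1 and LEU2 too. The rise of PDR12, a weak-acid exporter gene, and of the other groups is open on this point.

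Too few splits of the 6 libraries exist (10) for a share under 0.05: 1 split, the real one, reached 1469 genes, the highest other 0, and 1 split, the real one, reached 21 lists, the highest other 18. The 9 other splits, each with 2 libraries of a group against 1, gave 7 to 18 lists and no gene. Camera calls with the preset correlation are therefore weak support by themselves. Both genes were called higher in 3.949% of divergent neighbour pairs (43 of 1089, 95% Wilson interval 2.95 to 5.28), 2.83% of convergent pairs (33 of 1167, 2.02 to 3.94) and 2.77% of pairs on the same strand (56 of 2025, 2.14 to 3.57), intervals that overlap. The correlation of log2 fold changes across pairs was 0.191, 0.088 and 0.084 (permutation adjusted p = 0.0003, 0.002 and 0.0006 over 3 relations; the orientation of the top pairs had been seen first). In 57 pairs of ribosomal protein paralogs the less abundant copy had a mean log2 fold change -0.113 ± 0.658 (SD) from the other's (permutation p = 0.202, adjusted 0.404; -0.074, p = 0.356 without RPL7); its log2 fold change was the lower in 37 pairs, and the median difference was -0.128. The 88 ribosomal protein genes with an intron differed by -0.06 from the 47 without (permutation p = 0.431, adjusted 0.431).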
